A study of Homo sapiens with 7 samples.

How the data were processed

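RNA was measured on 7 expression arrays, 1 of undifferentiated H9 human embryonic stem (ES) cells and 6 of neural cells derived from them. Per the labels' protocols, total RNA was extracted with Trizol and RNeasy columns, amplified with an Ambion kit and labelled with biotin. The deposited values are signal intensities on a linear scale, 1 for each of 54675 probe sets on each array, and the submitters' processing notes name MAS5, the Affymetrix algorithm that condenses the probe pairs of a probe set into 1 background-corrected signal. Its version is not given in the sources used here, and detection calls were not used here. The deposited intensities had already been brought to 1 level per array: the mean after removal of 2% of values at each end lay between 500.05 and 500.06 on all 7. Such scaling by 1 factor per array assumes that total signal is comparable between cell types.

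The names of genes came from the platform annotation supplied with the table. A single gene symbol was given for 41097 probe sets, several symbols for 1801 and none for 11777; probe sets with several or no symbols were left out. By Entrez identifier, 41043 of the named probe sets matched the RefSeq gene table, and 0 symbols changed. The named probe sets covered 19775 genes, and each gene was represented by the probe set with the highest mean signal over the arrays. No per-sample column of the table was left unmatched to a sample.

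Each array was rescaled to the common trimmed mean, which changed almost nothing, and values were taken as log2(signal + 128), the offset being the pooled median signal of all arrays. The offset damps noise of dim probe sets, so a fold change is on that scale and understates the change of genes with low signal. A gene entered a test if its signal exceeded the pooled median on at least 1 array of the fit. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean), two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Called genes were also counted by whether they lay on the same side for all arrays compared. Passing the test nearly forces that, so these counts are no separate support. Depth has no counterpart in these data, and the number of arrays limits the precision.

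Groups were taken from the array titles: BASF (2 arrays, BASFP2 and BASFP3), SDJ (1, SDJP3), early (2, FM_Early as replicate 1 and FP_early as replicate 2), late (1, FL_Late) and undifferentiated (1). The title abbreviations are not explained in the labels and were used as names only. The neural arrays were compared with the undifferentiated array in a model with 5 residual degrees of freedom, in which the spread among the 6 neural arrays includes any differences in condition. The other comparisons came from 1 model of the 6 neural arrays with a mean for each of the 4 title groups; its 2 residual degrees of freedom come from the BASF pair and the early pair. The late array was set against the mean of the 3 BASF and SDJ arrays, each with equal weight. The members of a pair differ in a title letter or number of unknown meaning, so whether this spread is noise alone is not known. The undifferentiated, late and SDJ groups have 1 array each, which was assumed to vary like the others. Nothing in the labels says that arrays of a group came from separate cultures, so p-values of genes measure only the spread between these samples. eBayes borrows part of that spread from other genes. In the model of the 6 neural arrays it added 4.14 prior degrees of freedom to the 2 residual ones.

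Before the data were examined, 17 gene lists were fixed: pluripotency, neural progenitor, rosette, forebrain, midbrain and hindbrain, HOX, SHH response and ventral, Notch pathway, astroglia and radial glia, oligodendrocyte lineage, neuron, neural crest, mesenchyme, mesoderm and endoderm, proliferation, FGF and EGF response, and hypoxia and glycolysis. The rosette list is known from this study's own publication, so it was chosen on these samples. Some lists share members, and a shared gene counts in each. Examples are OLIG2 and NKX2-2 (SHH response and oligodendrocyte), HES1 and HES5 (Notch and neural progenitor) and FABP7 (neural progenitor and astroglia). LHX2 is in the rosette and forebrain lists, and SOX10 in the neural crest and oligodendrocyte lists. Lists were tested with camera, limma's competitive gene set test, at a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment was over the lists of a comparison. At the preset, the p-value weighs list genes against other genes and does not measure the spread between arrays. With an estimated correlation, it rests on the few residual degrees of freedom, so a list can hardly pass where these number 2. Named genes followed a rule fixed together with the lists. From each comparison it took the 8 highest and 8 lowest changes among called genes that moved the same way against every array of the other side, excluding placeholder symbols. From each list it added up to 4 called members with the largest changes, or at most 2 members with their values where none was called. For each pair of arrays without a test, it took the 6 largest differences each way among genes with a signal over 4 times the pooled median. List medians of those pairs were placed among 10000 random lists of equal size matched on mean signal.

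The fits were tested on simulated data in which 50 genes were changed at each of 4 known folds, at the spread of the real arrays. The changed genes were drawn only from genes with a mean log2 signal above the median, so the shares do not hold for dimmer genes. A true 2-fold change lies at the cut of a call, so its share reflects that cut as well as the spread. The larger simulated changes also ease the adjusted p of the smaller ones. Noise was drawn independently per gene from the moderated spread, so real data may hold more false calls. For neural against undifferentiated, among 15050 simulated genes, the share of changed genes called was 12% at 2-fold, 76% at 4-fold, 100% at 8-fold and 94% at 16-fold, with 3 false calls. For late against early, among 14526 genes, the shares were 56% at 2-fold and 100% at 4-fold, with 12 false calls. For late against BASF and SDJ, among 14561 genes, they were 44% at 2-fold and 98% at 4-fold, with 20 false calls. For SDJ against BASF, among 14526 genes, they were 44% at 2-fold and 100% at 4-fold, with 15 false calls. The alternatives tried were quantile normalization, the values as deposited, an offset of 64.1 or none with a floor of 1, no low-signal filter or one at 513, the mean of a gene's probe sets or every probe set on its own, eBayes without trend or with robust variances, the adjusted p alone, equal weights for BASF and SDJ, each array left out in turn, and each neural array in turn as a lone array. Leaving out each array in turn for the list tests that passed was chosen after the data were seen.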

Results

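Gene expression was compared on 7 arrays of H9 cells and their neural derivatives. H9 (WA-09) is an established human ES cell line that can be turned into neural rosettes, radial arrangements of early neuroepithelial cells. The array titles give 1 undifferentiated, 2 early, 1 late, 2 BASF and 1 SDJ array. The labels do not say which titles belong to the stage grown in FGF2 and EGF that the study also describes, so no title is assigned to it. Median signal per array ran from 113 on the late array to 143 on the SDJ array. The 3'/5' signal ratio of the ACTB control probe sets, which grows when RNA is shortened, was highest on the late array (6.51) and 3.63 to 5.18 on the other 6. The GAPDH ratio was also highest on the late array (1.40) and 1.10 to 1.31 elsewhere. The late array differed over 2-fold from the other neural arrays in 2321 to 2535 genes, whereas the 2 BASF arrays differed in 385 and the 2 early arrays in 294. Among the BASF, SDJ and early arrays, arrays of different groups differed in 235 to 1022 genes.

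**Figure D1:**
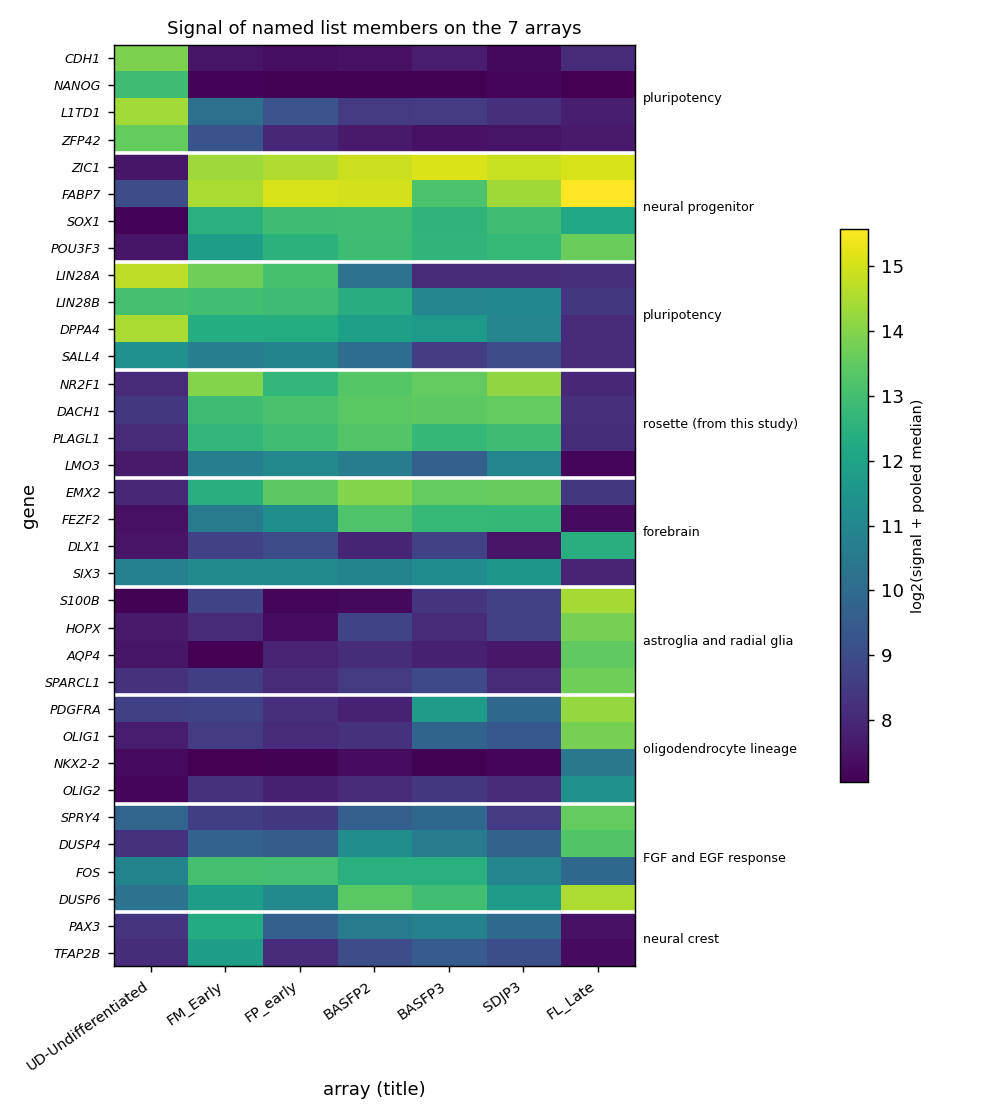
Signal of named members of the fixed gene lists on the 7 arrays. Color gives log2(signal + pooled median) of 1 probe set per gene. Columns run from the undifferentiated array over the early, BASF and SDJ arrays to the late array.

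On the neural arrays, 12 of 17 measured pluripotency genes were lower and 10 of 19 neural progenitor genes higher than on the undifferentiated array. NANOG, a core pluripotency transcription factor, was lower by -5.82 ± 0.18 log2 units (SE; 6 neural arrays against 1; adjusted p = 1.51e-05), and CDH1, the epithelial cadherin of ES cells, by -6.34 ± 0.31 (adjusted p = 9.95e-05). ZIC1, a zinc finger factor of early neural ectoderm, was higher by 7.25 ± 0.29 (adjusted p = 4.05e-05), and POU3F3, a POU factor of neural progenitors, by 5.18 ± 0.54. Of 15396 genes tested with limma, 381 were higher and 433 lower on the neural arrays, and all 814 lay on the same side on 6 of 6 neural arrays. Which direction held more calls depended on the setting: 548 higher and 235 lower with no offset, 446 and 395 with 0.5 times the offset, 401 and 328 with the stricter low-signal filter, and 910 and 727 without the late array.

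Of 17 measured pluripotency genes, 12 fell and 5 did not pass (13 fell when adjusted over the list alone). The list had an adjusted p of 7.22e-16, and adjusted p = 0.0695 with an estimated correlation. ZFP42, a zinc finger protein of ES cells, fell by 5.64 ± 0.61 log2 units and L1TD1, an RNA-binding protein of ES cells, by 5.65 ± 0.77. Outside the list, APELA, a peptide hormone made by ES cells, fell by 6.26 ± 0.62. Probe sets assigned to POU5F1B, POU5F1P3 and POU5F1P4 were lower (-5.85 ± 0.40, -5.48 ± 0.19 and -5.69 ± 0.34); they resemble POU5F1 in sequence, so which transcript they read is uncertain. LIN28A, an RNA-binding protein that blocks let-7 maturation, did not pass (-4.45 ± 2.21, adjusted p = 0.294). Its signal was 26481 on the undifferentiated array, 13143 and 8592 on the early arrays, 1078 and 147 on the BASF arrays, 153 on the SDJ array and 171 on the late array.

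Of 19 measured neural progenitor genes, 10 rose, 0 fell and 9 did not pass (13 rose when adjusted over the list alone). The list had an adjusted p of 1.13e-11, and adjusted p = 0.0219 with an estimated correlation. FABP7, a fatty acid binding protein of radial glia, rose by 5.54 ± 0.73, SOX1, a factor of the neural plate, by 5.53 ± 0.34, and HES5, a Notch target, by 4.70 ± 0.86 log2 units. SOX2, shared by ES cells and neural progenitors, did not pass (0.10 ± 0.23). Of 10 rosette genes, 1 rose and 9 did not pass (1 rose over the list alone), with a median of 3.33 and 10 of 10 above 0. That list was chosen by the study on these samples and is not independent evidence; its adjusted p was 0.000585, and adjusted p = 0.471 with an estimated correlation. LHX2, a LIM factor of the forebrain, rose by 5.04 ± 0.61, and without the late array, whose ACTB ratio was 6.51, all 10 rosette genes rose.

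Of 17 neuron genes, 3 rose and 14 did not pass (3 rose over the list alone), with an adjusted p of 0.000252, and adjusted p = 0.293 with an estimated correlation. MAP2 and DCX, microtubule proteins of neurons, rose by 4.64 ± 0.46 and 4.09 ± 0.49 log2 units, and ELAVL3, a neuronal RNA-binding protein, by 2.80 ± 0.62. GPM6A, a neuronal membrane glycoprotein outside the list, rose by 5.08 ± 0.72. Of 15 Notch pathway genes, 1 rose (3 over the list alone; adjusted p = 0.00144, and adjusted p = 0.205 with an estimated correlation). Of 12 mesenchyme genes, 3 fell (5 over the list alone; adjusted p = 0.0018, and adjusted p = 0.205 with an estimated correlation): COL6A3, a collagen chain (-3.74 ± 0.37), TAGLN, an actin-binding protein (-3.34 ± 0.40), and THY1, a surface glycoprotein (-1.57 ± 0.32). Of 13 hypoxia and glycolysis genes, 1 fell, EGLN3, a prolyl hydroxylase, to a level 2.82-fold lower (2 over the list alone; adjusted p = 0.0486, and adjusted p = 0.429 with an estimated correlation). That list no longer passed without early replicate 2 (adjusted p = 0.0693), nor with quantile normalization.

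The other lists did not pass as wholes. In the forebrain list, 1 of 13 rose and 1 fell (adjusted p = 0.439); the gene that fell was HESX1, a homeobox repressor of the anterior neural plate, by 2.15 ± 0.32 log2 units. Of 11 mesoderm and endoderm genes, CXCR4, a chemokine receptor also carried by neural cells, rose by 4.27 ± 0.58 and KDR, a VEGF receptor, fell by 2.44 ± 0.31 (adjusted p = 0.554). Of 14 FGF and EGF response genes, SPRED2, an inhibitor of MAP kinase signaling, rose by 1.80 ± 0.24 (adjusted p = 0.0540). Of 18 astroglia and radial glia genes 1 rose, FABP7 (adjusted p = 0.531). No gene passed in the midbrain and hindbrain (0.531), HOX (0.554), SHH response (0.531), oligodendrocyte (0.832), neural crest (0.931) and proliferation (0.109) lists, adjusted p of each list in parentheses. EN2 (1.52 ± 0.94), HOXB2 (1.61 ± 0.85), PTCH1 (0.95 ± 0.32), OLIG1 (1.96 ± 1.85, and 1.13 without the late array), PAX3 (1.76 ± 1.38) and AURKA (-1.16 ± 0.41) stand for them. Against EN2 and PAX3, other members of their lists went the other way, IRX2 (-1.25 ± 0.64) and ERBB3 (-2.25 ± 1.32). The number of calls was 439 without BASF replicate 1, 517 without BASF replicate 2, 441 without the SDJ array and 1637 without the late array. Of 26 named genes called, APELA, EGLN3, ELAVL3, HES5, KDR, SPRED2 and THY1 lost the call in at least 1 alternative setting, and of 11 named genes not called, ERBB3 and HOXB2 passed in at least 1.

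**Figure D2:**
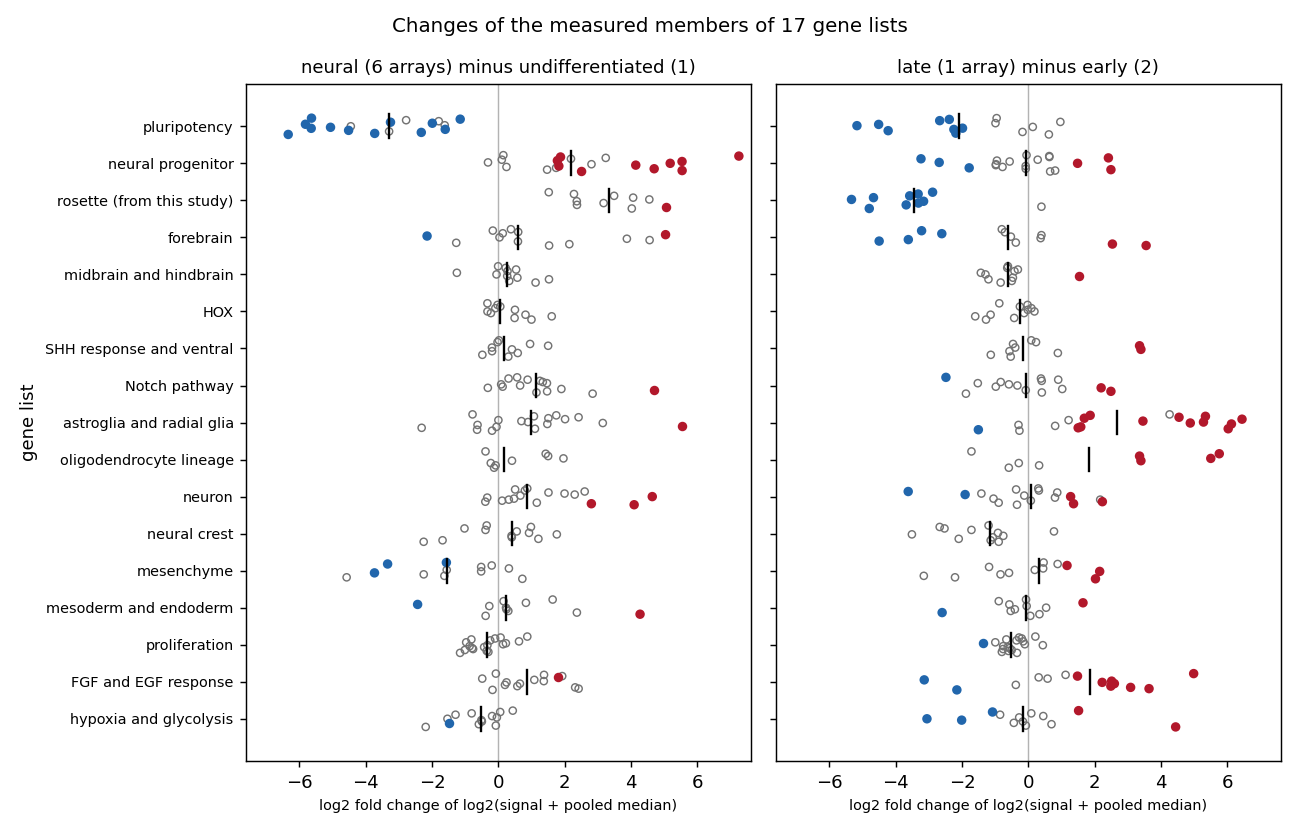
Log2 change of each measured member of the 17 gene lists. The left panel shows neural (6 arrays) minus undifferentiated (1), the right panel late (1) minus early (2). Filled red and blue points were called higher and lower, open grey points did not pass, and black bars are medians.

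Glial transcripts were higher and rosette transcripts lower on the late array than on the early arrays. S100B, a calcium-binding protein of astrocytes, was higher by 6.44 ± 0.73 log2 units (SE; 1 array against 2; adjusted p = 0.00399) and AQP4, the water channel of astrocytes, by 6.02 ± 0.37 (adjusted p = 0.000908). NR2F1, an orphan nuclear receptor, was lower by -5.33 ± 0.49 (adjusted p = 0.00215) and DACH1, a transcriptional cofactor, was 27.8-fold lower (log2 SE 0.15; adjusted p = 0.000669). Of 15021 genes tested with limma, 869 were higher and 1026 lower, all 1895 on the same side of both early arrays. The median change of all genes was -0.12, and the late array had the highest ACTB ratio (6.51).

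Of 18 astroglia and radial glia genes, 12 rose and 1 fell (13 and 1 over the list alone), with a median of 2.66, an adjusted p of 2.80e-08, and adjusted p = 0.386 with an estimated correlation. HOPX, a homeodomain protein of radial glia, rose by 6.12 ± 0.42, SPARCL1, a matrix protein of astrocytes, by 5.34 ± 0.31 and NFIB, a factor that promotes gliogenesis, by 5.28 ± 0.40 log2 units. The list member that fell was ALDOC, also a glycolytic enzyme (-1.51). PMP2, a myelin lipid-binding protein outside the list, rose by 6.65 ± 0.25, from signals of 17.2 and 5.8 on the early arrays to 13849 on the late array. Of 8 oligodendrocyte lineage genes, 4 rose (4 over the list alone; adjusted p = 0.0229, and adjusted p = 0.732 with an estimated correlation). They include OLIG1 (5.50 ± 0.60) and OLIG2 (3.35 ± 0.28), factors of oligodendrocyte precursors, PDGFRA (5.75 ± 1.39), their growth factor receptor, and NKX2-2 (3.39 ± 0.26), also a ventral factor. Of the 8, 5 lay above 0. The lowest was SOX10 (-1.72), with signals of 1613 and 11.3 on the early arrays and 21.7 on the late array. These genes were measured on the array with the ACTB ratio of 6.51.

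Of 10 rosette genes, 9 fell (9 over the list alone), with a median of -3.45, an adjusted p of 3.70e-07, and adjusted p = 0.584 with an estimated correlation. The study chose this list on these samples, and it is not independent evidence. PLAGL1, an imprinted zinc finger protein, fell by 4.67 ± 0.26 and LMO3, a LIM-only protein, by 3.69 ± 0.40 log2 units. Of 14 pluripotency genes, 8 fell (8 over the list alone; adjusted p = 0.00234, and adjusted p = 0.868 with an estimated correlation): LIN28A (-5.17 ± 0.80), LIN28B, its paralog (-4.52 ± 0.50), DPPA4, a chromatin protein of ES cells (-4.23 ± 0.18), and SALL4, a zinc finger factor (-2.68 ± 0.56), among others. Outside these lists, PRTG, a membrane protein of the immunoglobulin superfamily (-4.83 ± 0.43), and EPHA7, an ephrin receptor (-4.59 ± 0.39), fell. IRS4, an insulin receptor substrate (-4.64 ± 0.20), and FBLN1, a matrix protein (-4.68 ± 0.40), fell too. These falls were measured on the array with the ACTB ratio of 6.51.

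Of 14 FGF and EGF response genes, 8 rose and 2 fell (9 and 2 over the list alone), with an adjusted p of 0.000232, and adjusted p = 0.584 with an estimated correlation. SPRY4, a feedback inhibitor of receptor tyrosine kinases, rose by 4.98 ± 0.22, and DUSP4 and DUSP6, phosphatases of MAP kinases, rose by 3.64 ± 0.30 and 3.08 ± 0.30 log2 units. FOS, an immediate early gene, fell by 3.14 ± 0.15. Of 18 proliferation genes, 1 fell, MCM2, a replication helicase subunit, by 1.38 ± 0.20 (adjusted p = 0.0473, and adjusted p = 0.887 with an estimated correlation). Without early replicate 2 the proliferation list did not pass (adjusted p = 0.295). Of 13 hypoxia and glycolysis genes, 2 rose and 3 fell (adjusted p = 0.865). ADM, a vasoactive peptide, rose by 4.44 ± 0.55 and VEGFA, an angiogenic factor, by 1.51 ± 0.22, while LDHA, lactate dehydrogenase, fell by 3.06 ± 0.25 and HK2, a hexokinase, by 2.01 ± 0.27. The ACTB ratio of the late array was 6.51.

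The lists of regional identity did not pass as wholes. Of 12 forebrain genes, 2 rose and 4 fell (adjusted p = 0.322): EMX2 and FEZF2, factors of the cortical primordium, fell by 4.50 ± 0.41 and 3.62 ± 0.36 log2 units, SIX3 fell by 3.22 ± 0.21, and DLX1, a factor of the ventral forebrain, rose by 3.55 ± 0.35. Of 11 midbrain and hindbrain genes 1 rose, GBX2, by 1.53 ± 0.30 (adjusted p = 0.322), and of 11 HOX genes none passed (0.412). Of 10 SHH response genes 2 rose (adjusted p = 0.398), where the list median was -0.16, the mean 0.48 and the test direction up. Of 19 neural progenitor genes 3 rose and 3 fell (adjusted p = 0.915), with a median of -0.08 and test direction up: HES1 rose by 2.49 ± 0.55, SOX9 by 2.41 ± 0.62, SOX3 fell by 3.24 ± 0.45 and PROM1 by 2.69 ± 0.28. Of 15 Notch pathway genes 2 rose and 1 fell (adjusted p = 0.865): HEY2 rose by 2.19 ± 0.49 and NRARP fell by 2.49 ± 0.52. The 2 SHH response genes that rose were OLIG2 and NKX2-2, also members of the oligodendrocyte lineage list. HES1 is in both the neural progenitor and Notch pathway lists. The late array, on which these were measured, had the ACTB ratio of 6.51.

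Of 17 neuron genes 3 rose and 2 fell (adjusted p = 0.322; median 0.07, mean -0.02, test direction up). GAD1, a GABA-producing enzyme, rose by 2.23 ± 0.31 and ELAVL3 by 1.36 ± 0.35 log2 units, while STMN2, a tubulin-binding protein, fell by 3.62 ± 0.76 and NHLH1, a neurogenic factor, by 1.91 ± 0.48. Of 12 mesenchyme genes 3 rose (adjusted p = 0.322; median 0.32, mean -0.06, test direction up): DCN, a proteoglycan, by 2.15 ± 0.44, ACTA2, smooth muscle actin, by 2.02 ± 0.44 and PRRX1, a homeobox factor, by 1.16 ± 0.22. Of 11 mesoderm and endoderm genes EOMES, also a factor of cortical intermediate progenitors, fell by 2.60 ± 0.46 and MESP1 rose by 1.65 ± 0.29 (adjusted p = 0.865). Of 12 neural crest genes none passed (adjusted p = 0.227); PAX3 changed by -3.51 ± 0.95 (adjusted p = 0.0518; -2.19 without early replicate 1) and TFAP2B by -2.68 ± 1.32 (-0.83 without early replicate 1 and -4.52 without early replicate 2), and both were higher on early replicate 1 than on early replicate 2. Of 51 named genes called, ACTA2, DCN, ELAVL3, GBX2, HES1, HEY2, MESP1, NHLH1, NRARP, PDGFRA, PRRX1, SALL4, SOX9, STMN2 and VEGFA lost the call in at least 1 alternative setting. All 4 named genes not called, HOXA2, HOXB2, PAX3 and TFAP2B, passed in at least 1. Calls numbered 1176 with the mean of a gene's probe sets.

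Against the BASF and SDJ arrays, the late array again carried more glial and less rosette transcript, with the same late array and its ACTB ratio of 6.51 on 1 side. S100B was higher by 6.31 ± 0.69 log2 units (SE; 1 array against 3; adjusted p = 0.00311), AQP4 by 5.65 ± 0.35, and SCRG1, a glial transcript outside the lists, by 5.63 ± 0.75. RSPO2 and RSPO3, secreted enhancers of Wnt signaling, were lower by -6.34 ± 0.55 (adjusted p = 0.00147) and -5.44 ± 0.36. Of 15021 genes tested with limma, 857 were higher and 1150 lower, all 2007 on the same side of 3 of 3 arrays. NT5E, an ectonucleotidase, rose by 5.18 ± 0.24 and TFPI, a coagulation inhibitor, by 5.09 ± 0.46, while DMRT3, a factor of the dorsal telencephalon, fell by 5.37 ± 0.18.

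Of 18 astroglia and radial glia genes 12 rose and 1 fell (13 and 1 over the list alone; adjusted p = 1.93e-07, and adjusted p = 0.429 with an estimated correlation), among them HOPX (5.31 ± 0.40) and SPARCL1 (5.20 ± 0.30). Of 10 rosette genes 9 fell (9 over the list alone; adjusted p = 2.54e-07, and adjusted p = 0.609 with an estimated correlation), among them NR2F1 (-5.67 ± 0.46), DACH1 (-5.22 ± 0.14) and PLAGL1 (-4.82 ± 0.25). That list is not independent evidence, as the study chose it on these samples. Of 8 oligodendrocyte lineage genes 3 rose (4 rose and 1 fell over the list alone; adjusted p = 0.0355, and adjusted p = 0.762 with an estimated correlation), OLIG1 by 4.66 ± 0.57, OLIG2 by 3.16 ± 0.27 and NKX2-2 by 3.25 ± 0.25. Of 14 FGF and EGF response genes 8 rose and 2 fell (8 and 2 over the list alone; adjusted p = 0.00148, and adjusted p = 0.71 with an estimated correlation). SPRY4 rose by 4.19 ± 0.21, ETV5, a target of FGF signaling, by 3.20 ± 0.31 and EGFR by 2.68 ± 0.30. Each was measured on the array with the ACTB ratio of 6.51.

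The other lists did not pass as wholes. Of 14 pluripotency genes 5 fell (adjusted p = 0.0504), among them DPPA4 (-3.37 ± 0.17), LIN28B (-3.03 ± 0.47) and EPCAM, an epithelial adhesion molecule (-2.79 ± 0.23). Of 19 neural progenitor genes 4 fell (adjusted p = 0.845; median 0.11, mean -0.09, test direction down), among them SOX3 (-2.37 ± 0.42), PAX6 (-1.05 ± 0.24) and SOX11 (-1.04 ± 0.20). Of 12 forebrain genes 2 rose and 4 fell (adjusted p = 0.481), with FEZF2 lower by -5.63 ± 0.34, EMX2 by -5.27 ± 0.39, and DLX1 and DLX2 higher by 4.38 ± 0.33 and 3.42 ± 0.28. Of 11 midbrain and hindbrain genes 1 rose and 2 fell, EN2 by 2.10 ± 0.50 and CNPY1 by 2.05 ± 0.33 (adjusted p = 0.481). Of 11 HOX genes 2 fell, HOXB2 by 2.16 ± 0.54 log2 units and HOXB3 4.01-fold (adjusted p = 0.481). Of 15 Notch pathway genes 4 fell, among them NRARP by 2.36 ± 0.49 and DLL1, a ligand, by 1.86 ± 0.50 (adjusted p = 0.832; median 0.11, mean -0.15, test direction down). The late array's ACTB ratio was 6.51.

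Of 17 neuron genes 2 rose and 4 fell (adjusted p = 0.827; median 0.17, mean -0.63, test direction down), with STMN2 lower by -4.89 ± 0.72 and SLC17A6, a vesicular glutamate transporter, by -3.17 ± 0.61. Of 12 mesenchyme genes 2 rose and 2 fell (adjusted p = 0.481; median 0.14, mean -0.08, test direction up): DCN and ACTA2 rose by 2.97 ± 0.42 and 2.95 ± 0.41, and the collagen chains COL1A2 and COL1A1 fell by 5.13 ± 0.86 and 3.22 ± 0.72. Of 13 hypoxia and glycolysis genes 1 rose, ADM by 4.70 ± 0.52, and 2 fell, LDHA by 2.87 ± 0.23 and HK2 by 2.15 ± 0.26 (adjusted p = 0.481). EOMES fell by 3.32 ± 0.43, the only call of 11 mesoderm and endoderm genes (adjusted p = 0.481), and 2 of 10 SHH response genes rose (0.481). No gene passed in the neural crest (12 measured; 0.481) and proliferation (18 measured; 0.481) lists; PAX3 changed by -2.99 ± 0.89 and MKI67 by 0.58 ± 0.25. Of 56 named genes called, COL1A1, DLL1, EGFR, ELAVL4, EN2, GBX2, HK2, HOXB2, HOXB3, MFNG, NKX2-2, NRARP, PAX6, SOX11, SOX3 and USP44 lost the call in at least 1 alternative setting, and of 4 not called, PAX3 and MSX1 passed in at least 1. Calls numbered 1255 with the mean of a gene's probe sets and 3055 by adjusted p alone.

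No gene passed between the SDJ array and the BASF arrays. FOS had the lowest adjusted p (-1.55 ± 0.15 log2 units, SE; 1 array against 2; adjusted p = 0.424), and SPRY2, a feedback inhibitor of FGF signaling, differed by -1.65 ± 0.32. TTR, a thyroid hormone carrier, differed by 3.02 ± 1.45 (0.98 without BASF replicate 1 and 5.06 without BASF replicate 2), and PAX7 by -1.96 ± 0.73 (-2.87 and -1.05 in the same order). HEY2 differed by 1.88 ± 0.49, EN2 by -1.38 ± 0.53 and CNPY1 by -1.39 ± 0.35. With limma, 0 of 15021 genes were called and 636 (4.23%) had an unadjusted p under 0.05. In simulated data of this design, 44% of 2-fold changes of brighter genes were called. That share reflects the 2-fold cut of a call as well as the spread, since the median estimate of these genes was 1.01 log2 units. The simulation also held changes of up to 16-fold, which ease the adjusted p. Differences of 2-fold and less are thus not excluded. Nor are larger ones, since TTR at 3.02 log2 units was not called. In the data, 129 genes differed over 2-fold and none was called. The BASF arrays, which gave part of the spread, differed over 2-fold from each other in 385 genes. The SDJ array differed from BASF replicate 1 in 307 and from BASF replicate 2 in 235.

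By list, 14 FGF and EGF response genes had a median of -1.11 (8 lower over the list alone; adjusted p = 3.28e-15, and adjusted p = 0.491 with an estimated correlation). The 11 midbrain and hindbrain genes had -0.61 (adjusted p = 0.00264, and adjusted p = 0.731 with an estimated correlation). The 14 pluripotency genes had -0.33 (adjusted p = 0.00341, and adjusted p = 0.731 with an estimated correlation). The 13 hypoxia and glycolysis genes had -0.29 (adjusted p = 0.00992, and adjusted p = 0.731 with an estimated correlation). The 15 Notch pathway genes had 0.42 (adjusted p = 0.0194, and adjusted p = 0.731 with an estimated correlation), and the 17 neuron genes 0.36 (adjusted p = 0.0355, and adjusted p = 0.810 with an estimated correlation). None of the remaining 11 lists passed. At the preset correlation, these tests weigh list genes against other genes, not array against array. Only the FGF and EGF response list passed whichever BASF array was left out. Without BASF replicate 1, the pluripotency median was -0.09 (adjusted p = 0.439) and the hypoxia and glycolysis median -0.14 (adjusted p = 0.119). Without BASF replicate 2, these were -0.65 and -0.46, the midbrain and hindbrain median was -0.40 (adjusted p = 0.175), and the neuron median 0.35 (adjusted p = 0.234). The Notch pathway median was then -0.10, with a mean of 0.04 and test direction up (adjusted p = 0.901). Without BASF replicate 1, LIN28A went from -1.04 to 0.03 and ACTA2 from -0.51 to 0.06. Without BASF replicate 2, HES5 went from 0.79 to -0.37 and TNC from -1.35 to 0.71.

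Within the early pair, neural crest genes were lower on early replicate 2 than on early replicate 1; with 1 array each, no test was made. The list median was -2.37 log2 units, with 11 of 12 genes over 2-fold lower, and matched random lists gave -0.22 to 0.19. SOX10, a crest and oligodendrocyte factor, differed by -3.64 (signal 11.3 against 1613), TFAP2B, a crest factor, by -3.69, ERBB3, a neuregulin receptor, by -3.54 and ETS1 by -3.77. Mesenchyme genes had a median of -0.90, with LUM, a proteoglycan, at -3.16, and neuron genes -0.73, midbrain and hindbrain genes -0.57, oligodendrocyte lineage genes -0.48 and hypoxia genes -0.47, each below its random lists. Forebrain (0.42), proliferation (0.40), rosette (0.30) and neural progenitor (0.24) medians lay above them, with LHX2 at 1.56 and NR2E1, a receptor of forebrain progenitors, at 2.08. In all, 50 genes were over 2-fold higher and 244 lower.

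Within the BASF pair, also without a test, the median of the Notch pathway genes was lower on BASF replicate 2 than on BASF replicate 1. It was -0.78 log2 units, with 7 of 15 genes over 2-fold lower and 1 over 2-fold higher, and matched random lists gave -0.19 to 0.18. HES5 differed by -2.30, while NOTCH2, a receptor of the pathway, went the other way by 1.03 (signal 12409 against 6021). LIN28A differed by -2.13. Rosette (-0.67), neural progenitor (-0.39), proliferation (-0.34), hypoxia (-0.34), FGF and EGF response (-0.25), pluripotency (-0.23) and mesenchyme (-0.20) medians also lay below their random lists, and midbrain and hindbrain genes (0.40) above. TRPM3, a cation channel, was higher by 4.38, COLEC12, a scavenger receptor, by 4.22, TNC, a matrix protein of radial glia, by 4.11, TTR by 4.08 and PDGFRA by 3.90. In all, 237 genes were over 2-fold higher and 148 lower.

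**Figure D3:**
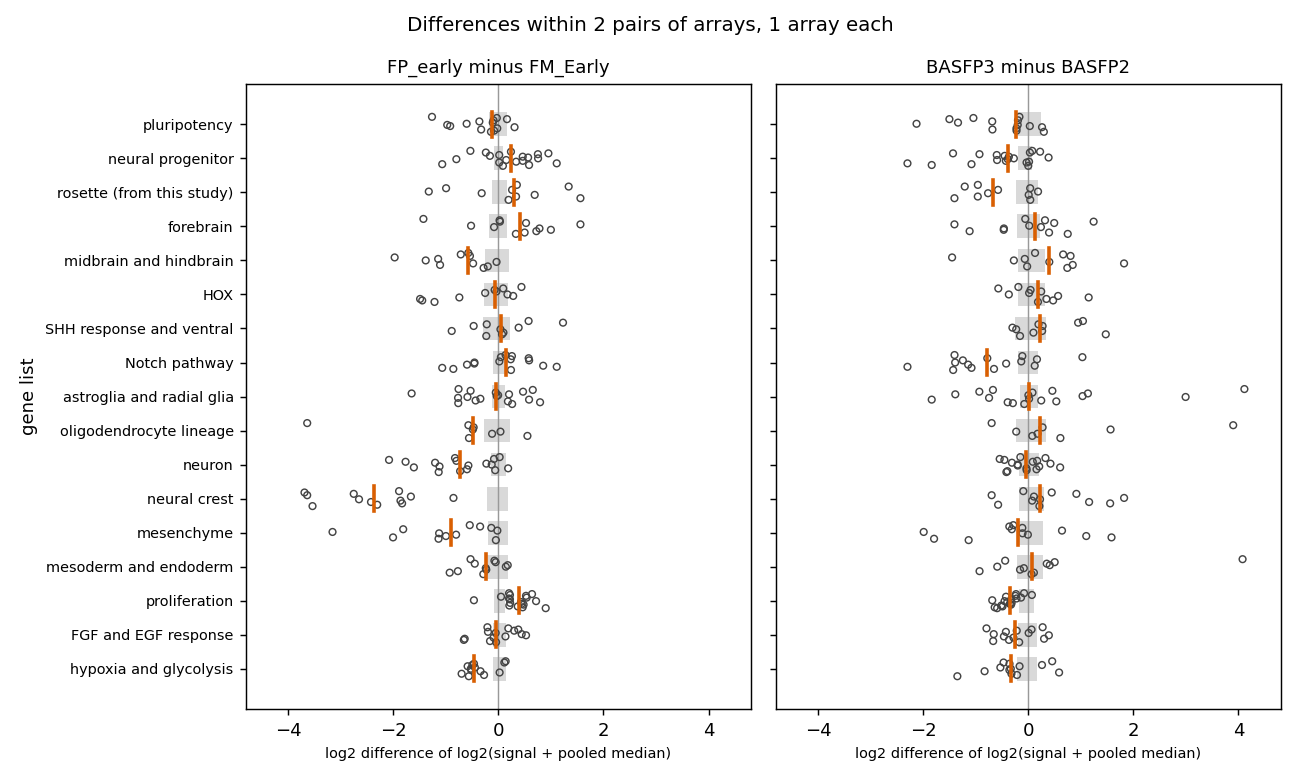
Log2 differences between the arrays of each pair for the members of the gene lists. Early replicate 2 minus early replicate 1 is at left and BASF replicate 2 minus BASF replicate 1 at right. Orange bars are list medians, and grey bars the central 95% of 10000 random lists matched on mean signal.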

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

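The tests of RNA integrity and of the mesoderm and endoderm list were chosen only after the result was seen; those of second probe sets and the second crest list were written before theirs, and so was that of the glycolytic enzymes, though ALDOC, ENO1 and PGK1 among them are members of the fixed lists, whose results had been seen. Of 22 measures per array tested for a value far from the rest, 4 stood out, all on the late array. They were the mean log2 signal of the rosette list (8.24), of the forebrain list (9.08) and of the astroglia and radial glia list (12.5), and the mean correlation with the other neural arrays (0.862). The study chose the rosette list on these samples, so its value is not independent evidence.

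The late array stood apart from the early arrays. Of 1059 second probe sets of called genes, 971 (91.7%) moved the same way, against 68.2% for genes not called, which argues against noise of individual probe sets. Lower RNA integrity adds no transcript, and it is argued against for the astroglia and radial glia genes. Of these, 12 of 18 rose, and the median of 2.66 lay above random lists at -0.40 to 0.21. The count and the median were known when that test was written, so passing its bound is no separate evidence. For the other rises and the falls, lower RNA integrity stays open. Of 869 rises, 83 went from below the pooled median on both early arrays to over 4 times it, but were picked by their size. The ACTB ratio of the late array was 1.38 times the early mean, from 1 array. The difference in stage that the titles name was not tested apart from any difference between individual cultures.

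Neural crest genes were lower on early replicate 2 than on early replicate 1. As a hypothesis, early replicate 1 could hold cells of a neural crest type. A second list of crest genes had a median of -1.56, with 9 of 9 below 0 and random lists at -0.26 to 0.23. Of these genes, 4 had signals of at most 513, 4 times the pooled median, on both early arrays. More cells of every other type stays open. The mesoderm and endoderm median lay 2.13 above the crest median, but 9 of the 11 mesoderm and endoderm genes had signals of at most 513 on both early arrays. The mesenchyme, neuron, and midbrain and hindbrain medians were lower too. Several crest genes are also expressed in the dorsal neural tube or in oligodendrocyte precursors. No sort is given in the sources used here that would remove such cells.

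LDHA and HK2 were lower on the late array. If the loss lay with these probe sets alone, the other glycolytic enzymes would stay within random lists, and their median was -0.19 against -0.43 to 0.33. By the bound written beforehand that favors the explanation, but 7 of 12 lay below 0 and the others above, and ALDOC and PKM passed as lower, so the label was set to undecided after the values were seen. LDHA has 1 probe set, and the other probe sets of HK2 changed by -0.49 and -0.83 at low signal.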

How the results depend on the processing

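All alternatives were planned before the data were examined, except that leaving out arrays for the list tests was chosen after the data were seen. Leaving out each neural array in turn moved the calls of the neural comparison between 439 and 1637. With 1 neural array in turn as a lone array against the other 5, calls numbered 0 and 0 for the BASF arrays, 1 and 0 for the early arrays, 0 for the SDJ array and 1576 for the late array. Late against early gave 1176 calls with the mean of a gene's probe sets and 3114 with every probe set. Late against BASF and SDJ gave 1255 and 3210, and 3055 by adjusted p alone. With an estimated correlation, the lists past the threshold went from 7 to 1 for the neural comparison and from 6 to 0 for late against early. They went from 4 to 0 for late against BASF and SDJ and from 6 to 0 for SDJ against BASF. The astroglia and radial glia list, lost for late against early, had an estimated correlation of -0.020, below the preset 0.01. Correlation between genes alone therefore does not account for that loss. With an estimated correlation, camera also rests on the residual degrees of freedom, only 2 in the model of the 6 neural arrays. A list can then hardly pass at any correlation, so these losses do not show that gene correlation undid the lists. Of the 34 named genes not called for SDJ against BASF, 4 turned when a BASF array was left out. Without BASF replicate 1 and then without BASF replicate 2, the values were SDJ against BASF: LIN28A (0.0290 and -2.10), SDJ against BASF: ACTA2 (0.0567 and -1.08), SDJ against BASF: HES5 (1.94 and -0.37) and SDJ against BASF: TNC (-3.41 and 0.71). No paired analysis was possible because the BASF and SDJ groups share only 1 title number and the other groups have none.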

Other observations

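The genes in this paragraph and the next were chosen after their values were seen. HMGA2, a chromatin protein of fetal progenitors, fell by 4.53 ± 0.17 log2 units from early to late (signals 16505 and 16155 against 582). IGF2BP1, a fetal RNA-binding protein, fell by 4.45 ± 0.24 and TRIM71, a let-7 target, by 4.55 ± 0.59. FZD5, a Wnt receptor, fell by 4.24 ± 0.30. KCNJ10, a potassium channel of astrocytes, rose by 4.65 ± 0.24, CDKN1A, an inhibitor of the cell cycle, by 3.44 ± 0.41 and B2M, a subunit of MHC class I, by 1.52 ± 0.16. The late array had the ACTB ratio of 6.51.

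TTR, abundant in choroid plexus and liver, had signals of 6428 on BASF replicate 2 and 12833 on the SDJ array but 260 on BASF replicate 1. TRPM3, a cation channel, had 3037 on BASF replicate 2 and 1650 on the SDJ array. RSPO2 had 7191 and 10732 on the BASF arrays, 14453 on the SDJ array, 1258 and 365 on the early arrays and 1.6 on the late array. No test was made of these patterns.

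The test in this paragraph was written before its lists were looked at. The hypothesis was that dorsal forebrain genes would lie lower and ventral forebrain genes higher on the late array than on the early arrays. Of 2 further lists, 6 dorsal genes had a mean change of -0.98 with 6 below 0, and 7 ventral genes had -0.44 with 5 below 0 (exact permutation p = 0.167 over 1716 arrangements). The test did not separate the lists, and it decides nothing, since most members had low signal. Low signal was taken as at most 513, 4 times the pooled median, on the early and late arrays. By that cut, 5 of the 6 dorsal and 5 of the 7 ventral genes were low. WNT8B was among them, with signals of 439 and 310 on the early arrays and 12.8 on the late array. DMRTA2 and WNT8B (dorsal) and ZFHX3 (ventral) passed as lower. NEUROG1, GAD2 and NKX6-2 are also members of the fixed lists.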
